A study of Mus musculus with 6 samples.

How the data were processed

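Total RNA of 6 mouse embryonic stem (ES) cell samples was labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. 3 samples came from a Dppa4 knockout cell line and 3 from the Dppa4 hemizygous cell line it was compared with. Each group is thus 1 cell line, and both lines were grown on mouse embryonic fibroblast feeder cells, per the series' design text. The authors deposited 1 table of log2 expression values per probe set and array, normalized by RMA (robust multi-array average) per the submitters' processing notes. The RMA software, its version, its background and summarisation settings and the chip definition are not given in the sources used here. That the scale is log2 was read from the values, which ran from 2.12 to 13.98 and carried 2 decimals. RMA gives the arrays a shared distribution, so a shift of most transcripts in 1 direction would not be visible in these values. Array medians lay between 4.21 and 4.25.

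The table held 45101 probe sets, of which 64 control probe sets were left out and 45037 were tested. The platform annotation given with the table named 1 gene for 34945 of these, several for 932 and none for 9160; those in the last class are unnamed here, not without a gene. Gene IDs of 34741 probe sets were matched to a RefSeq gene table of the assembly GRCm38.p6, which was used only for symbols, chromosomes and neighbouring genes. Each of 18193 genes was represented by a single probe set, the one with the highest mean over the 6 arrays among those with exactly 1 gene. No gene is named from a probe set with several genes. The background level was the 95th percentile of the means of 80 probe sets of olfactory and vomeronasal receptor genes, 3.78 on the log2 scale. The higher of the group means lay above it for 13378 genes. Where each array of the dimmer group lay at or below that level, the fold is given as a bound, "at least N-fold". It sets the brighter group's mean against the mean, over the dimmer arrays, of the higher of the background level and the value itself. The number of arrays limits the precision of all values.

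Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over the 45037 probe sets and a threshold of 0.05. A second count required a log2 change of at least 1. Changes are knockout minus parental on the log2 scale throughout, with the standard error (SE) of the moderated fit or the standard deviation (SD) of the 3 arrays. Adjusted p-values of genes are limma's. With 3 arrays against 3, an exact permutation test of a single value cannot give a two-sided p below 0.1. 22 gene lists with 589 entries, 534 of them measured, were tested with limma's camera at a preset correlation of 0.01. Some genes, such as Dnmt3l, stood in more than 1 list and were counted in each. They were adjusted over the 22 lists and repeated with an estimated correlation and with fry. Chromosomes with at least 20 measured genes were tested in the same way. The design, the gene lists, the rule for named genes and the alternatives listed at the end were fixed before the data were examined; the closing section names the covariates, tests and rules that were set later.

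The genes named are Dppa4 and Dppa2, then the 15 largest rises and 15 largest falls among genes with an adjusted p under 0.05, no overlap between the groups and the higher mean above background. From each list, up to 4 members that met these criteria with the largest changes were added or, where none did, the 2 members with the highest level. Pou5f1, Nanog and Sox2 were named whatever their result. Other names are said to have been chosen after their values were seen. The labels number the replicates of each group but do not state that they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. No 2 arrays held the same values.

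The procedure was tested on simulated data for the knockout and parental comparison over 45037 probe sets, in 5 runs with 200 changed probe sets each. It recovered 93.6% of changes of log2 1 and 99.0% of changes of log2 2, with 45 false calls in all runs. A list shifted by 0.5 was called in 20 of 20 runs, and 1 of 420 unshifted lists was called. The simulated noise was independent between genes, and its size did not depend on their level. The rates for single probe sets may therefore differ on the real arrays, and those for lists do not hold where genes vary together. Splits of the real arrays other than knockout against parental gave up to 6 called lists. Alternatives were quantile normalization applied again, array medians subtracted, the replicate number as a block, an intensity trend with a robust prior, probe sets above background only, probe sets without the x_at and s_at endings, a fit without moderation, limma's treat at 1.5-fold, the mean of all probe sets of a gene, other probe sets of a gene, and leaving out each array in turn. Covariates for variation within groups and for the feeder genes were added after the data were seen. The result of 1 further test, of a hypothesis on a signalling pathway, is not reported here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.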

Results

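Gene expression was measured in mouse ES cells with a knockout of Dppa4 and in the hemizygous parental line, which retains 1 copy of the gene. Dppa4 encodes a chromatin-associated nuclear protein of pluripotent cells. The comparison addresses whether ES cells depend on this gene for their expression state. Each group held 3 arrays with RMA values for 45037 probe sets, and array pairs correlated between 0.994 and 0.997 across probe sets. Both cultures contained feeder fibroblasts, and fibroblast transcripts were abundant on all arrays. Col1a2, a collagen gene, had a mean of 12.61 ± 0.08 (SD, n = 3) in parental and 12.71 ± 0.07 (SD, n = 3) in knockout samples.

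The targeted gene was measured first. Dppa4 (probe set 1429597_at, chromosome 16) read 10.30, 10.35 and 10.45 in the parental samples and 8.68, 8.84 and 8.68 in the knockout samples. The log2 change was -1.63 (SE 0.08, adjusted p = 0.000112, limma), which left 32.2% of the parental signal. Every knockout array was below every parental array, for which the exact permutation p was 0.1, the smallest that 3 against 3 can give. The remaining signal of 8.73 ± 0.09 (SD, n = 3) was above the background level of 3.78. Where the probe set lies relative to the deleted part is not known here. A probe set outside that part would check nothing, so this value bears on the labels only through its direction. Dppa2, the neighbouring gene and known binding partner of Dppa4, changed by -0.08 (SE 0.12, adjusted p = 0.890) on 1453223_s_at and by -0.22 (SE 0.12, adjusted p = 0.622) on 1429654_at.

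The 15 largest named falls came from genes with parental means of 5.32 to 9.61, several of them known from germ cells. AF067061 had the largest fall among named genes, from 9.10 ± 0.36 to 4.53 ± 0.26 (SD, n = 3), a 23.8-fold difference. Its only probe set assigned to a single gene has the x_at ending, so this fall could not be checked without such probe sets. Gm20767, another gene of chromosome 13, was at least 11.7-fold lower. Syce1, a synaptonemal complex gene of meiosis, was at least 9.38-fold lower, and Mael, a gene of the germ cell piRNA pathway, at least 8.02-fold. In all 4, the knockout and parental values did not overlap and the adjusted p was 0.000106 or lower (limma). Falls continued with the deubiquitinase gene Usp17la (-3.09, at least 4.90-fold), the carbonic anhydrase gene Car4 (-2.52, at least 4.09-fold) and Sohlh2 (-2.39), a transcription factor of germ cells. The other probe set of Car4 was at least 2.49-fold lower but did not pass (adjusted p = 0.0679). Calb2, which encodes calretinin, and Dazl, an RNA-binding protein gene of germ cells, both changed by -2.14, the latter by at least 3.10-fold. Klhl13, a ubiquitin ligase adaptor gene, changed by -2.07, and the drug efflux gene Abcb1a by -2.02. The sperm gene Spesp1 changed by -1.92, although its other probe set, below background, gave -0.13 (adjusted p = 0.755). The 15 named falls were completed by 1700029P11Rik (-1.84), the clathrin adaptor gene Ap1s3 (-1.72) and the non-coding gene Gm21283 (-1.70, at least 2.89-fold).

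In total, 181 of 45037 probe sets passed the test (limma), 150 lower and 31 higher in knockout cells, and 82 of them changed at least 2-fold, 80 lower and 2 higher. By gene, 93 fell and 17 rose, of 18193 tested. Of the named genes that passed, 15 had other probe sets of their own, 21 in all, of which 20 had the same direction and 8 also passed. Groups did not overlap for 14.2% of probe sets, where chance gives 10%. Larger changes than those of named genes were seen on probe sets that the annotation assigns to several genes: 1443961_at, with 7 genes, changed by -6.53, and 1457033_at, with 6 genes, was at least 42.2-fold lower. The count of 181 fell to 70, 96 and 102 without parental replicate 1, 2 or 3 and to 73, 112 and 79 without knockout replicate 1, 2 or 3. An intensity trend with a robust prior gave 312, and a fit without moderation gave 1. The count of 82 fell to 54 without parental replicate 1 or without knockout replicate 1, and treat at 1.5-fold gave 32. Car4 lost its call without parental replicate 1 (-2.41, adjusted p = 0.0883), knockout replicate 1 (-2.35, adjusted p = 0.0762) or knockout replicate 2 (-2.52, adjusted p = 0.0582).

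**Figure D1:**
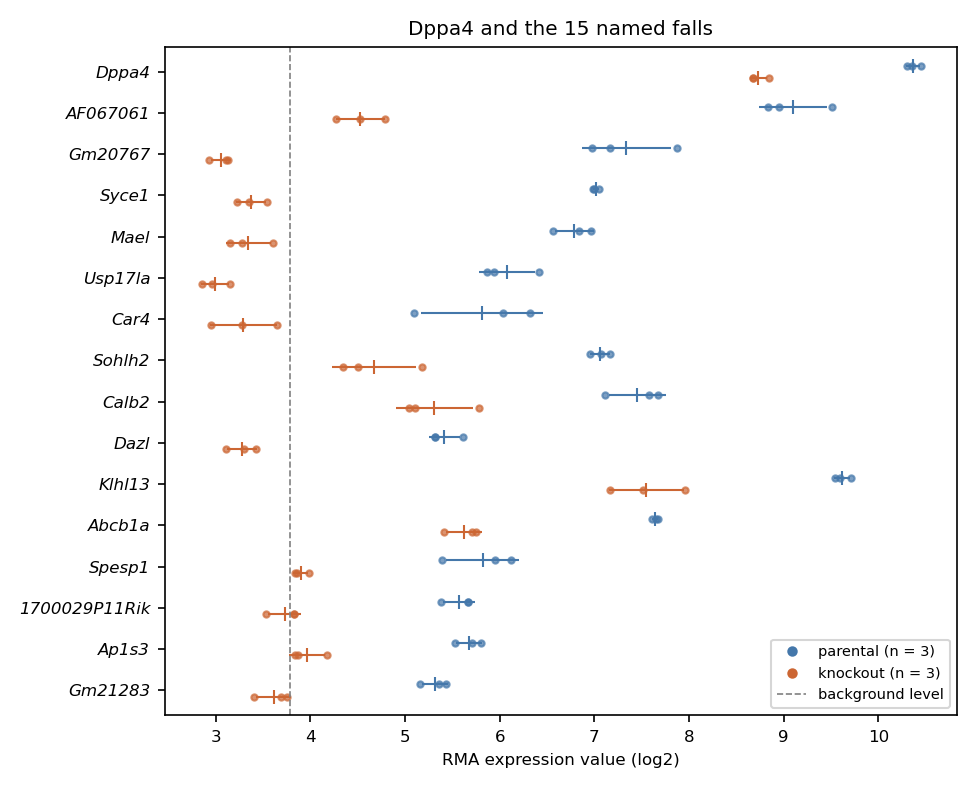
RMA values (log2, horizontal axis) of Dppa4 and the 15 named falls, with 1 point per array, a bar for the mean and a line for the SD of 3 arrays, parental above knockout in each line. The dashed line is the background level of 3.78, and all knockout points of Syce1, Mael and Dazl lie below it.

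**Figure D2:**
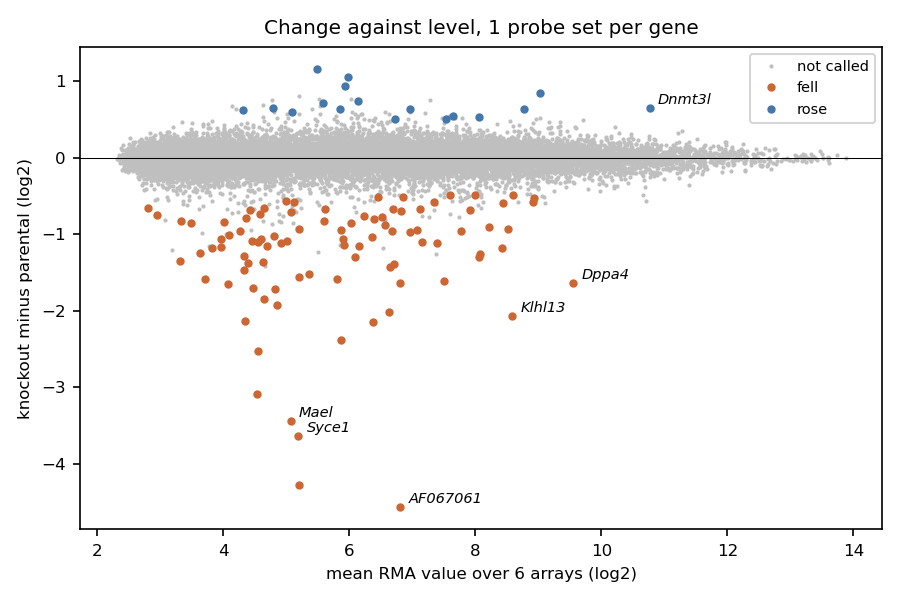
Knockout minus parental change (log2, vertical axis) against the mean RMA value over 6 arrays (log2, horizontal axis) for 18193 genes with 1 probe set each. Coloured points are the 93 genes that fell and the 17 that rose.

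Germ cell genes fell as a group. Of 31 measured members of this list, 7 fell, none rose and 24 did not pass; adjusted over the list alone, 17 fell. Besides Syce1, Mael and Dazl, the RNA helicase gene Ddx4 was at least 2.16-fold lower (-1.65, SE 0.19, adjusted p = 0.0124, limma). Ddx4 lost its call without parental replicate 1 (adjusted p = 0.0841), parental replicate 2 (0.0513), parental replicate 3 (0.0564) or knockout replicate 3 (0.0643). The remaining falls, named after their values were seen, were Kit (-0.94), a receptor tyrosine kinase gene, Slc25a31 (at least 1.15-fold) and Tex19.1 (-1.30). Kit lost its call without parental replicate 1 (adjusted p = 0.0508) or knockout replicate 1 (0.0510). Tex19.1 lost it without parental replicate 1 (0.0998), 2 (0.114) or 3 (0.115) and without knockout replicate 1 (0.154) or 3 (0.167). The mean of the 23 members above background in either group went from 5.39 ± 0.09 to 4.52 ± 0.06 (SD, n = 3), while over all 31 the mean change was -0.70 and the median -0.38. Camera gave an adjusted p of 2.34e-17 for the list, and an adjusted p = 0.0380 with an estimated correlation.

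Genes of the 2-cell-like state, a transient state of ES cells resembling the 2-cell embryo, also fell. Of 15 measured members, 2 fell and 13 did not pass; adjusted over the list alone, 7 fell. Usp17la and Tcstv3 (-0.65, adjusted p = 0.00887) were those that fell; Tcstv3 lay below background in both groups and was named after its value was seen. Its adjusted p was 0.0589 without parental replicate 1 and 0.0549 without knockout replicate 1. A further 7 members were found only on probe sets shared with other genes and were not counted. Shared probe sets annotated with some of them fell strongly: 1457033_at was at least 42.2-fold lower, 1443961_at changed by -6.53 and 1444529_at by -2.80. These falls cannot be assigned to a single gene, and not all of the 7 lay on a probe set that passed. The mean of the 6 members above background in either group went from 5.67 ± 0.08 to 4.71 ± 0.06 (SD, n = 3), while over all 15 the mean change was -0.52 and the median -0.30. Camera gave an adjusted p of 4.92e-08, and an adjusted p = 0.0380 with an estimated correlation.

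Rises were fewer and smaller. Timm8a2, a mitochondrial import gene, rose from 4.90 ± 0.26 to 6.07 ± 0.06 (SD, n = 3), a 2.24-fold difference, and Iqcg rose 2.08-fold (adjusted p = 0.00792 and 0.00656, limma). The acyl-CoA thioesterase gene Acot1 rose by 0.94, Fam25c by 0.84, the ciliary transport gene Ift122 by 0.74 and the cGMP phosphodiesterase gene Pde9a by 0.71. Dnmt3l, a cofactor of de novo DNA methylation, rose by 0.65 (SE 0.09, adjusted p = 0.0318) from an already high 10.44, and 5730507C01Rik rose by 0.65. Slco4a1, Prr23a3 and Trnau1ap each rose by 0.64, Nrros by 0.63, Oscp1 by 0.60, 2610524H06Rik by 0.55 and Acaa2, a mitochondrial thiolase gene of fatty acid oxidation, by 0.53. The other probe set of Slco4a1 gave 0.17 (adjusted p = 0.692) and that of Ift122 0.63 (0.0875), those of Acaa2 gave 0.42 (0.0855) and 0.60 (0.0233), and that of Trnau1ap gave 0.58 (0.0230). Timm8a2 and Dnmt3l each had only a probe set with the s_at ending, so neither rise could be checked without such probe sets. Of the 15 rises, 13 lost their call when some single array was left out. Iqcg and Acot1 did not. Without parental replicate 1, 2 or 3, the calls lost were 13, 10 and 11, with adjusted p up to 0.180, 0.140 and 0.154. Without knockout replicate 1, 2 or 3 they were 11, 10 and 11, with adjusted p up to 0.172, 0.131 and 0.173.

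**Figure D3:**
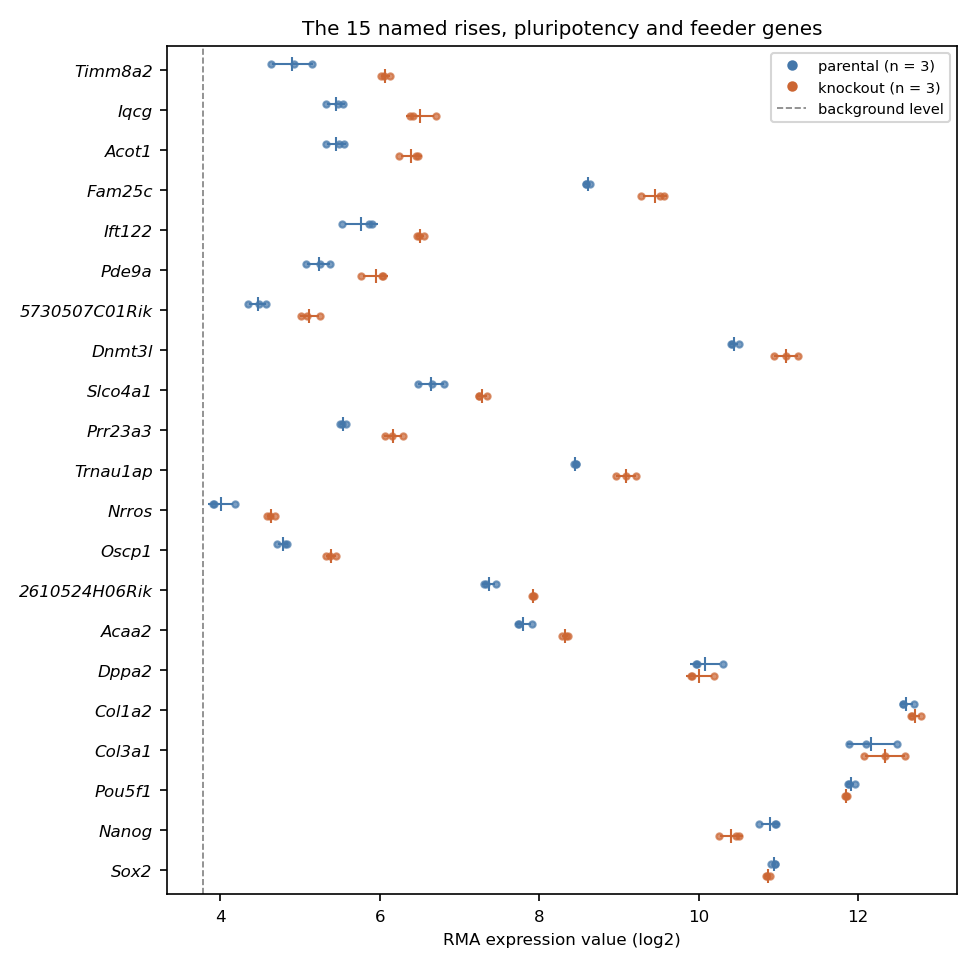
RMA values (log2, horizontal axis) of the 15 named rises and of Dppa2, Col1a2, Col3a1, Pou5f1, Nanog and Sox2, with 1 point per array, a bar for the mean and a line for the SD of 3 arrays, parental above knockout in each line. The dashed line is the background level of 3.78; Pou5f1 and Sox2 differ by -0.06 and -0.08 between groups.

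The central pluripotency genes stayed at high levels in both groups. Pou5f1 was 11.91 ± 0.05 in parental and 11.85 ± 0.02 in knockout samples (SD, n = 3; change -0.06, SE 0.07, adjusted p = 0.852, limma). Sox2 changed by -0.08 (SE 0.07, adjusted p = 0.797) and Nanog by -0.49 (SE 0.10, adjusted p = 0.122), lower in 3 of 3 knockout samples. Of 30 measured members of the pluripotency list, 1 rose, Dnmt3l, and 29 did not pass; adjusted over the list alone, 6 fell. These 6, named after their values were seen, were Fbxo15 (-0.57), Dppa3 (-0.53), Nanog, Prdm14 (-0.49), Gdf3 (-0.37) and Klf2 (-0.35). Camera called the list lower, with an adjusted p of 0.00998, but an adjusted p = 0.477 with an estimated correlation. It lost its call without knockout replicate 1 (adjusted p = 0.0520) or 3 (0.0592), and with the feeder gene mean as a covariate (-0.08, adjusted p = 0.0734). Dnmt3l lost its call without parental replicate 1 (0.115), 2 (0.123) or 3 (0.130) and without knockout replicate 1 (0.147) or 2 (0.0782).

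Feeder fibroblast genes differed slightly in the opposite direction. Their mean was 10.60 ± 0.08 in parental and 10.69 ± 0.13 in knockout samples (SD, n = 3; exact permutation p = 0.3), and 0 of 35 measured members passed the test of limma; at an unadjusted p under 0.05, 1 was higher and 0 lower. Camera called the list higher, with an adjusted p of 0.00998, but an adjusted p = 0.477 with an estimated correlation. It lost its call without parental replicate 1 (adjusted p = 0.0581) or knockout replicate 1 (0.217). Cholesterol synthesis genes were likewise called higher by camera (median 0.12, adjusted p = 0.00329; adjusted p = 0.477 with an estimated correlation; 0.0581 without parental replicate 1). Of their 19 members 0 passed the test of limma, and 6 were higher at an unadjusted p under 0.05. Their most abundant members, Hmgcs1 and Fdps, changed by 0.12 (adjusted p = 0.731) and 0.20 (adjusted p = 0.493). In the trophoblast list, 1 of 23 members fell, the X-linked homeobox gene Rhox9 (-1.11, adjusted p = 0.0368), and adjusted over the list alone 5 fell. Camera gave that list an adjusted p of 0.0386, and an adjusted p = 0.349 with an estimated correlation. Without parental replicate 1 or 2 its adjusted p was 0.0581 and 0.118, and without knockout replicate 1 or 2 it was 0.0520 and 0.0746. Rhox9 lost its call without parental replicate 1 (0.121) or 2 (0.145) and without knockout replicate 1 (0.102), 2 (0.127) or 3 (0.171).

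None of the other 16 lists was called by camera over the 6 arrays. Without parental replicate 2, the cell cycle list (adjusted p = 0.0337) and the glycolysis list (0.0195) were called. Without knockout replicate 1 the neighbours of Dppa4 were (0.0448), and without knockout replicate 2 the cell cycle (0.0129), DNA methylation (0.0466) and Hox (0.0254) lists were. The 6 called lists fell to 3 without parental replicate 1. Single members fell in some of the 16 lists that were not called: the neuronal tubulin gene Tubb3 (-0.88), the imprinted amino acid transporter gene Slc38a4 (-0.90), the heterochromatin protein gene Cbx5 (-0.53) and the Y-linked gene Uba1y (at least 1.10-fold). The other 4 probe sets of Cbx5 gave 0.09, -0.19, -0.12 and -0.07, none of which passed, and the other probe set of Uba1y gave -0.13 (adjusted p = 0.791). Slc38a4 gave -0.63 (adjusted p = 0.162) on its other probe set. Cbx5 lost its call without any 1 of the 6 arrays (adjusted p 0.0598 to 0.179). Slc38a4 lost it without parental replicate 1 (0.140) or 3 (0.140) and without knockout replicate 1 (0.0733), 2 (0.0963) or 3 (0.155), and Uba1y without parental replicate 1 (0.0839), 2 (0.106) or 3 (0.116) and knockout replicate 1 (0.151) or 3 (0.163). Dnmt3l was the member that rose in the DNA methylation and silencing list. Lists without any call among their members were represented by their most abundant genes. These were Hspa5 (0.04) and Asns (0.02) for the stress response, Pcna (-0.09) and Cdc20 (0.02) for the cell cycle, Sparc (0.06) and Lamb1 (0.06) for endoderm, and Morc1 (0.17) for the neighbours of Dppa4. For adhesion they were Vim (0.05) and Fn1 (0.10), for Hox genes Hoxc6 (0.04) and Hoxc9 (0.02), for glycolysis Pgk1 (0.12) and Ldha (0.06), and for the interferon list Ifitm3 (0.01) and B2m (0.01). Egr1 (0.13) and Fos (0.11) represented the LIF response, Ccng1 (0.03) and Cdkn1a (0.03) the p53 targets, Dnmt3b (0.17) and Sox4 (-0.03) the primed epiblast, and Pdgfra (0.21) and Bmp4 (0.51) the mesoderm; the lowest adjusted p among these was 0.0793, for Bmp4. For Y-linked genes, the median was 0.22, the mean -0.01 and the direction of the test upward (adjusted p = 0.641).

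**Figure D4:**
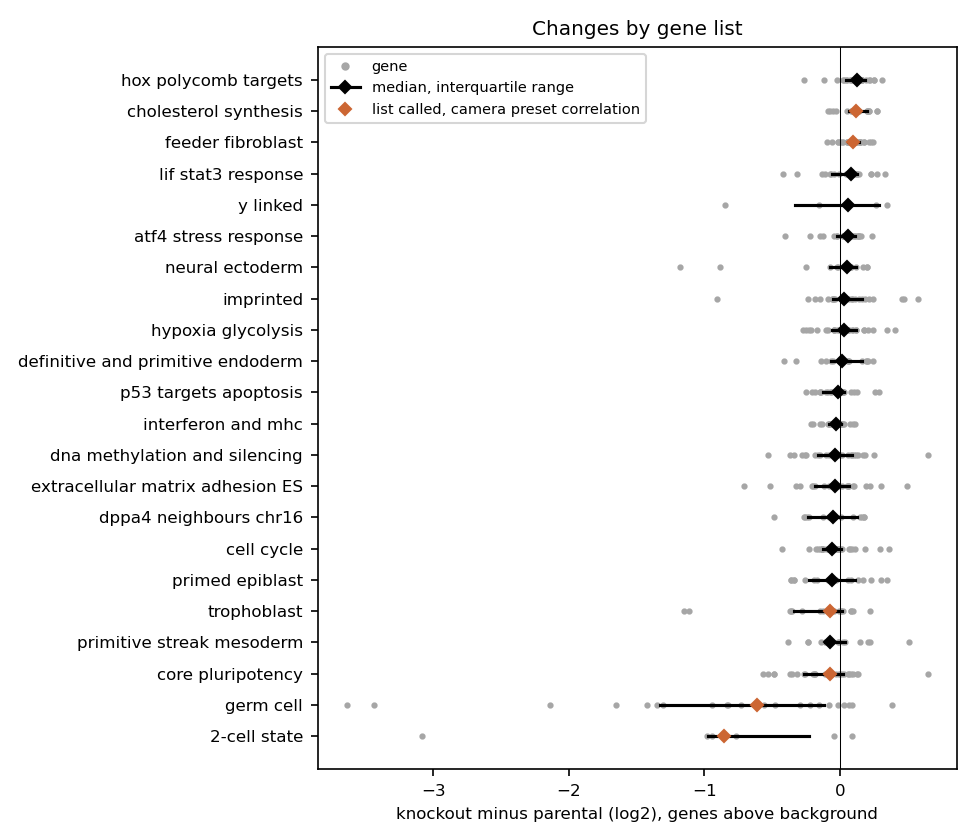
Knockout minus parental change (log2, horizontal axis) of genes above background in the 22 lists, with 1 grey point per gene, a diamond for the median and a line for the interquartile range. Orange marks the 6 lists called by camera over all measured members at the preset correlation, of which the germ cell and 2-cell state lists were also called with an estimated correlation.

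No chromosome was shifted as a whole. Of 20 chromosomes tested with limma's camera over 18029 placed genes, 0 were called, 0 had an unadjusted p under 0.05 and the lowest unadjusted p was 0.472. With an estimated correlation the count was also 0.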

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

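The covariates for variation within groups and for the feeder gene mean were chosen after the data were seen; the other settings were not. The lists of germ cell genes (-0.728 to -0.662 without 1 array) and 2-cell state genes (-0.536 to -0.491) were called under every alternative run, and 0 chromosomes were called by camera under any. Dppa4 stayed called, at -1.69 to -1.59 without 1 array and -1.58 with the feeder covariate. Of the 181 probe sets called, 81 were among the 88 (6 higher, 82 lower) called with the replicate block and 180 among the 312 (80 higher, 232 lower) called with an intensity trend and robust prior. The ordinary equal-variance test called 1, which rose and was not among the 181, and leaving out 1 array gave 70 to 112. The feeder covariate gave 129 (20 higher, 109 lower), of which 109 were shared, and the remaining settings gave 162 to 243. Probe sets changed at least 2-fold numbered 82, against 32 with treat and 54 to 73 without 1 array. The replicate numbers did not pair the arrays: same-number correlations of deviations were 0.112, -0.364 and -0.287, and not every array correlated best with its own number. Deviations of parental replicate 3 and knockout replicate 2 correlated at 0.379, and those of parental replicate 2 and knockout replicate 3 at 0.371. A block by replicate number does not capture these pairs. With the block, 12 of the 15 named rises and 2 of the 15 falls lost their call (Calb2, adjusted p = 0.0541; Car4, 0.0729), and with the feeder covariate 8 rises and 0 falls did (limma). Of the other genes reported as fallen, the block ended the calls of Kit (0.0509), Tex19.1 (0.0921), Tcstv3 (0.0721), Rnf17 (0.0852), Cyct (0.0921), Psma8 (0.0636) and Cbx5 (0.186), and the feeder covariate those of Aurkc (0.0573), Rhox9 (0.0613), Slc38a4 (0.0806), Uba1y (0.0968) and Cbx5 (0.108).

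The 6 called lists became 2 with an estimated correlation, 2 with fry, 4 with the feeder covariate and 3 to 8 without 1 array. The feeder list had no result with the feeder covariate, which is its own mean, so only the core pluripotency call was lost there. Shifts are the mean change of a list minus that of other genes. The calls of 4 lists, given here by their shift, were lost with camera at an estimated correlation (first adjusted p) and with fry (second), which tests a list for a change of its own and not against other genes. These were cholesterol synthesis (0.1208, adjusted p = 0.477 and 0.314), core pluripotency (-0.1121, 0.477 and 0.171), feeder fibroblast (0.1003, 0.477 and 0.513) and trophoblast genes (-0.1506, 0.349 and 0.171). The mixed test of fry, for changes in either direction, called 10 lists. It called core pluripotency (adjusted p = 2.68e-05) and trophoblast genes (0.0177), but not cholesterol synthesis (0.0875) or feeder fibroblast genes (0.780). The trophoblast call was also lost with the within-group covariate (-0.1506, 0.0573) and the core pluripotency call with the feeder covariate (-0.084, 0.0734). Hox genes were called among probe sets above background (0.1163, 0.0169). Signs changed with the feeder covariate for the cell cycle (0.0113), DNA methylation (0.0346), hypoxia (-0.0254), p53 (0.0142) and Y-linked (0.0606) lists, among probe sets above background for endoderm (0.0095), and with the mean of all probe sets of a gene for DNA methylation (0.0013). The mesoderm list changed sign with quantile normalization (0.0021) and without x_at and s_at probe sets (0.0017). Ranges without 1 array were -0.07 to 0.0092 (cell cycle), 0.0807 to 0.1748 (cholesterol), -0.1485 to -0.0938 (core pluripotency), -0.0833 to 0.0013 (DNA methylation), -0.0962 to -0.0368 (Dppa4 neighbours), 0.0525 to 0.1726 (feeder), 0.0441 to 0.1052 (Hox), -0.0233 to 0.1154 (hypoxia), -0.0894 to 0.0239 (interferon), -0.0705 to 0.0544 (p53), -0.1037 to 0.0342 (primed epiblast), -0.0208 to 0.0079 (mesoderm), -0.056 to 0.037 (Y-linked) and -0.2251 to -0.1068 (trophoblast).

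Among named genes, only Cbx5 changed sign from a called value, and no changed sign was itself called. Without x_at and s_at probe sets, Cdc20 gave -0.07 and Hoxc6 -0.1033. AF067061, Timm8a2 and Dnmt3l had no probe set without these endings and were not measured in that setting. With the feeder covariate, the values were -0.045 (Asns), -0.2669 (B2m), -0.0197 (Cdkn1a), 0.0409 (Dppa2), -0.0297 (Hoxc6), -0.0074 (Hoxc9), -0.0973 (Ifitm3), -0.036 (Sparc) and -0.0189 (Vim). On other probe sets they were -0.07 (Cdc20), -0.0233 (Hmgcs1), -0.02 and -0.0867 (Sparc), -0.0667 (Lamb1), 0.0933 (Cbx5), -0.26 (Fn1), -0.0567 (Col1a2), -0.1033 and -0.0167 (Hoxc6), -0.18 and -0.0467 (Ccng1), -0.0167 (Cdkn1a) and 0.05, 0.21 and 0.2833 (Sox4). Ranges without 1 array were -0.0667 to 0.0883 (Asns), -0.185 to 0.255 (B2m), -0.0667 to 0.1217 (Ccng1), -0.055 to 0.0667 (Cdc20), -0.0317 to 0.0733 (Cdkn1a), -0.1733 to 0.0283 (Dppa2), -0.0017 to 0.0983 (Hoxc6), -0.015 to 0.055 (Hoxc9), -0.0733 to 0.1067 (Ifitm3), -0.0933 to 0.0517 (Sox4) and -0.0867 to 0.1433 (Vim). A further 13 genes moved by over 1.5 times without changing sign when 1 array was left out, 0 of them called by limma over all arrays, such as Pdgfra (0.04 to 0.325), Dnmt3b (0.0583 to 0.2533), Egr1 (0.0283 to 0.2133) and Fn1 (0.03 to 0.23). The cause was not tested for any of these differences. Signal over background limits the falls whose knockout values lie near 3.78, for which the fold is only a bound. Lists without called chromosomes and the mean of the Dppa4 probe sets were not run, because no chromosome was called and Dppa4 had 1 probe set.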

Other observations

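Of the tests in this part, those of signal shared between gene copies, of the lists against genes of like level, of the ES cell share, of the number of X-linked genes and of the Rhox cluster were chosen after the result, or part of it, was seen; the others were not. How far a scaling must move values before it decides anything was also set afterwards. The genes in the next paragraph and Rhox5 were named after their values were seen.

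Further genes with known roles in the germ line lay outside the lists and fell. The piRNA-related gene Rnf17 fell by 1.10 (SE 0.14, adjusted p = 0.0161, limma), Stk31 was at least 1.39-fold lower (adjusted p = 0.000658) and the meiotic kinase gene Aurkc fell by 1.28 (adjusted p = 0.0386). The testis cytochrome gene Cyct was at least 1.55-fold lower (adjusted p = 0.0183), and Psma8, a proteasome subunit gene of the testis, fell by 0.96 (adjusted p = 0.0130). In each of these, all 3 knockout values were below all 3 parental values. Of these 5, Stk31 kept its call without any 1 of the arrays. Rnf17 lost it without parental replicate 1, 2 or 3 (adjusted p = 0.0936, 0.0549 and 0.0739) and without knockout replicate 1 or 3 (0.0873 and 0.0730), and its other probe sets gave -1.12 (0.0120), -0.89 (0.0555) and -0.56 (0.265). Psma8 lost it without parental replicate 1, 2 or 3 (0.0594, 0.0618 and 0.0630) and without knockout replicate 1 or 3 (0.0821 and 0.0558). Cyct lost it without parental replicate 1 (0.0780) or knockout replicate 1 (0.103) or 3 (0.0995), and Aurkc without any 1 of the 6 arrays (0.0539 to 0.161). No enrichment of a theme was tested with them.

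Arrays also differed within groups. The first component of the deviations from the group means held 42.2% of that variance. Computed without the feeder genes, its scores correlated over the 6 arrays with the feeder gene mean, taken as each array's deviation from its group mean. Pearson r was 0.934 (exact permutation p = 0.0556) and Spearman rho 0.829 (exact permutation p = 0.111), where the smallest possible p was 0.0278. The other measures below were taken as deviations from the group means in the same way. The adjusted p over 4 such relations was 0.222, and r was 0.759 without the 2 farthest arrays. The relations with actin 3' minus 5' signal (r = -0.760, rho = -0.771), Gapdh 3' minus 5' signal (r = 0.535, rho = 0.600) and the pluripotency gene mean (r = -0.355, rho = -0.143) had exact permutation p for r of 0.167, 0.361 and 0.639. Those for rho were 0.167, 0.278 and 0.861. Without the 2 farthest arrays r was -0.399, 0.660 and 0.177, and the adjusted p were 0.334, 0.481 and 0.639.

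The first pattern is that falls outnumbered rises, with germ cell and 2-cell state genes among them. Fewer feeder cells in the knockout cultures would lower fibroblast genes, but their median change was 0.0967 (95% bootstrap interval over genes 0.0733 to 0.120). Between arrays the list mean was 10.60 ± 0.08 in parental and 10.69 ± 0.13 in knockout samples (SD, n = 3, exact permutation p = 0.3). The list's shift stayed positive without any 1 array, at 0.0525 to 0.1726. The 95% intervals of changes in this part were taken over genes and do not measure the spread between arrays. Signal shared between gene copies was examined on probe sets of 1 gene without the x_at and s_at endings. Over all measured members, the germ cell list shifted by -0.69 there (95% interval -1.03 to -0.396) and the 2-cell state list by -0.5187 (-0.942 to -0.199). Probe sets with these endings thus did not carry the shifts. The main fit already used probe sets of 1 gene, and 1443961_at, with 7 genes, has neither ending. The test therefore cannot decide on shared signal, which stays open. A lower ES cell share was taken to need a median pluripotency change below -0.3; it was -0.0733 (95% interval -0.195 to -0.0033), an interval that excludes -0.3 but not the bound of -0.1 also set, and the rule that the interval must exclude -0.3 was written after the value was seen. Scaling is argued against for the germ cell and 2-cell state lists, which lay -0.684 (95% interval -1.03 to -0.390) and -0.5093 (-0.926 to -0.203) from genes of like level on the same arrays, but stays open for the excess of falls, because other scalings, with falls at least 4.26 times the rises, moved changes by a median of only 0.01; with 1 knockout line, loss of Dppa4 and any other difference between the 2 lines cannot be told apart, so a role of Dppa4 is only a hypothesis.

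The second pattern is X-linked genes among the falls, such as Klhl13 and Rhox5 (-1.62). Of 88 falls above background 11 were X-linked (12.5%), against 420 of 13313 genes (3.15%); the odds ratio was 4.48 (95% interval 2.13 to 8.54) and the two-sided Fisher's exact p was 9.73e-05, or 0.00195 adjusted over 20 chromosomes. Lower dosage of the whole chromosome would move its median, but X-linked minus autosomal was 0.0067 (95% interval over genes -0.0067 to 0.0217). Without the Rhox genes, neighbours on the chromosome, 8 of 85 falls were X-linked (9.41%, against 3.13% of genes). The odds ratio was then 3.26 (95% interval 1.35 to 6.82, Fisher's exact p = 0.00502, adjusted 0.1004). The share among falls thus stayed higher without that cluster, but did not pass after adjustment over the chromosomes. Chance, the Rhox cluster and another difference between the lines therefore stay open, since the test treats genes as independent and the excess was noticed and tested on the same data.

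Chance was examined over the 10 splits of the 6 arrays, too few for a share under 0.05. Only the real split, 1 of the 10, gave as many as 181 probe sets with limma, and the highest other split gave 0. Every other split put arrays of both lines into each group, so a difference between the lines added to the spread within its groups. Its low counts therefore do not show what chance alone would give. At an unadjusted p under 0.05 the real split gave 4274 and the highest other, parental replicates 1 and 3 with knockout replicate 2, gave 5182. Probe sets changed at least 2-fold numbered 82 in the real split and 0 in the highest other; at an unadjusted p under 0.05 they numbered 95 and 34. For lists, 2 of the 10 splits gave as many as the real 6, and the highest other split also gave 6. For chromosomes, all 10 splits gave 0 with camera, also at an unadjusted p under 0.05.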
